A study of Homo sapiens with 6 samples.

How the data were processed

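RNA was sequenced from motor neurons derived from H9 human embryonic stem cells, in 3 libraries kept under simulated microgravity (SMG) on a 2D clinostat and 3 kept at normal gravity (NG). Per the labels' protocols, the libraries were made from total RNA with an mRNA library kit. The time spent on the clinostat is not given in the sources used here. The deposited table holds raw counts, whole numbers per Ensembl gene and library, that the authors made from their reads. HISAT2, SAMtools, featureCounts, DESeq2 and the genome build hg19 are named per the submitters' processing notes. Their versions, the annotation, the use of strand and the treatment of reads that map to several places are not given in the sources used here.

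The table had 57820 genes, of which 36299 had a count in at least 1 library. A symbol was found for 51996 in a table of gene names and for 52338 after names from GENCODE 29 were added. GENCODE 29 is built on another genome build than the deposited table, so it was used for names, gene types, exon overlap between genes and the length and GC content of each gene's longest transcript, and no coordinates are given. Each column matched 1 sample's title. Total counts ranged from 16329907 to 22685870 per library. At this depth the median SE of a log2 fold change was 0.0524 for genes with a mean of 10 CPM or more, and the biological coefficient of variation was 0.0346.

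Groups were taken from the labels. Genes were filtered with edgeR's filterByExpr at its default settings, which left 17803, scaled by TMM and tested between SMG and NG with edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of single genes come from this test unless another is named. CPM values are TMM-scaled. The 55 gene lists were fixed before the data were examined, as were the tests and the rule for named genes. Lists with at least 5 tested members, 49 in all, were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 49 lists. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list's genes moved further than the other genes, and fry whether they moved, on balance, in a direction. The list members NEFL, LHX1, PECAM1, SPON1 and H3C2 matched no gene and are not reported.

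The genes named were, first, the 10 with the highest and the 10 with the lowest fold change among genes with a symbol that passed the test, had a mean of at least 2 CPM and had groups that did not overlap. From each list came up to 4 members that passed where the list was called and up to 2 elsewhere. To these were added 10 fixed genes (MNX1, ISL1, CHAT, SLC18A3, LHX3, TUBB3, NEFL, OLIG2, SOX2 and MKI67). The text gives values for a part of them, and adds members named because they did not pass. Genes of the sex chromosomes used to tell sex were left out.

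Results were recomputed with DESeq2, with limma-voom, with DESeq2's size factors, upper quartile or library size scaling, without a filter, with a filter of at least 1 CPM in 3 samples, without robust estimation, with the replicate number as a block, without each library in turn, and for lists with a prior count of 0.5. Alternatives added after the data were seen removed the trend of each library with transcript length and GC content, fitted as natural splines and entered as offsets, or kept protein-coding genes alone. The same scripts were first tested on simulated data. Counts were drawn for 17570 genes from the means and library sizes of this comparison, with 200 genes changed by known folds. EdgeR recovered 60% of the genes changed 1.2-fold, 96% of those changed 1.5-fold, and 100% of those changed 2-fold and 4-fold, with 7 false calls (3.78% of calls). Far fewer genes changed in this simulation than in the data, so its share of false calls need not hold there. In a second simulation of 41 lists, genes were drawn independently and 1 list was shifted 1.2-fold. Camera gave that list an adjusted p of 5.11e-30 with the preset correlation and 0.00815 with an estimated one, and called 0 unchanged lists. The estimated form was thus the weaker test in this simulation. Genes that change together were not simulated, so it does not show how often the preset form calls unchanged lists in these data. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.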

Results

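The data are bulk RNA sequencing counts from motor neurons derived from H9, an established line of human embryonic stem cells. Motor neuron progenitors had been differentiated with retinoic acid and SAG, an agonist of Hedgehog signalling. One group, simulated microgravity (SMG), was turned on a 2D clinostat, a device that rotates a culture so that the direction of gravity keeps changing relative to the cells, and the other, normal gravity (NG), was not. Each group had 3 libraries. The total count per library was 21386253, 16329907 and 16600001 in NG and 20986483, 22267155 and 22685870 in SMG. The labels do not say that the libraries came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom from 1.60 to 3.38), and each was counted as a sample of its own. Levels are given as CPM, counts relative to the library total after TMM scaling, as mean ± SD, and log2 fold changes as SMG minus NG ± SE, with n = 3 per group throughout.

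The comparison of SMG with NG asks which genes differ between motor neurons under simulated microgravity and motor neurons at normal gravity. Nearly all tested members of the hypoxia target and glycolysis lists fixed beforehand fell in SMG. PFKFB4 was at -2.04 ± 0.05 and HK2 at -1.83 ± 0.04 on the log2 scale. A second set of 22 hypoxia targets, drawn up after that fall was seen, had 12 lower and 4 higher. The deepest falls among the named genes were those of BHLHE40 (-4.18 ± 0.14), a transcriptional repressor, and the immediate early gene FOS (-3.00 ± 0.12). Genes of motor neuron identity, ion channels and the neuronal cytoskeleton were more often higher in SMG, mostly by small amounts. FOXP1, ALDH1A2 and SLC18A3, at 0.66 to 0.87, were the largest rises of 15 tested identity genes, whose median was 0.22, and MECOM fell (-0.40). After removal of a trend with transcript length and GC content, described below, the median was 0.08 for identity, 0.10 for channels and 0.12 for the cytoskeleton. Genes of cytosolic ribosomal proteins, nuclear-encoded respiratory complexes and the cell cycle were more often lower, with smaller median falls than the hypoxia and glycolysis lists. With an estimated correlation between genes, only the hypoxia and glycolysis lists passed (adjusted p = 0.0314 each), and the lists of the other groups named here had adjusted p from 0.0896 to 0.253. The estimated correlation was below the preset 0.01 for motor neuron identity (0.00979), the cytoskeleton (-0.00117) and the cell cycle (-0.0263). Their higher adjusted p therefore does not come from a larger correlation. The same holds for hypoxia targets (0.00936) and glycolysis (0.00937), whose adjusted p rose to 0.0314 from 5.84e-16 and 1.73e-14. The estimated correlation was above 0.01 for channels (0.0704), ribosomal proteins (0.0774) and respiratory complexes (0.0477 and 0.0727). How much of the rise in their adjusted p comes from correlation was not tested. A higher adjusted p in this form is thus not by itself a sign of correlated genes.

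Of 17803 genes tested, 6376 (35.8%) passed edgeR's quasi-likelihood test, 3080 higher and 3296 lower in SMG. Most of these differences were small. The median fold of the changed genes was 1.19 in either direction, and 5719 of them (89.7%) changed by less than 1.5-fold. At least 2-fold, 78 genes were higher and 88 lower. Among genes with a mean of 2 CPM or more, 35 were at least 2-fold lower and 1 was at least 2-fold higher, and 13 of the 35 belonged to the hypoxia or glycolysis lists. The 1 higher gene, the long non-coding ENSG00000270127, went from 1.52 ± 0.304 to 3.44 ± 0.215 CPM and is named after its values were seen. The counts at 2-fold depended on weakly expressed genes, and a filter of at least 1 CPM in 3 samples gave 24 higher and 52 lower. The groups did not overlap in 8240 tested genes (46.3%), where chance gives 10%. The first principal component separated the groups and held 73.8% of the variance.

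The hypoxia target list had 20 tested members, of which 19 fell and 0 rose (19 and 0 adjusted over the list alone), 7 of them at least 2-fold. Its median log2 fold change was -0.89, and it was called by camera with an adjusted p of 5.84e-16. PFKFB4, which sets the level of an activator of glycolysis, fell from 91.6 ± 2.51 to 22.2 ± 1.03 CPM (log2 fold change -2.04 ± 0.05). BNIP3, a mitophagy receptor, fell from 268 ± 1.56 to 88.2 ± 3.03 CPM (-1.60 ± 0.04). PDK1, the kinase that restrains pyruvate entry into mitochondria, fell from 157 to 57.1 CPM (-1.46 ± 0.04). ADM, the secreted peptide adrenomedullin, fell from 4.39 ± 0.612 to 0.765 ± 0.176 CPM (-2.50 ± 0.20). ANGPTL4 did not pass, at 0.35 (edgeR adjusted p = 0.454).

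The glycolysis list had 19 tested members, of which 17 fell and 0 rose (17 and 0 adjusted over the list alone). Its median was -0.58 with a camera adjusted p of 1.73e-14. HK2, the hexokinase of the entry step, fell from 245 ± 1.66 to 68.7 ± 1.68 CPM (-1.83 ± 0.04). LDHA, which makes lactate from pyruvate, fell from 228 to 111 CPM (-1.04 ± 0.04), PGK1 from 624 to 307 CPM (-1.02 ± 0.04) and the enolase ENO1 from 1955 to 974 CPM (-1.01 ± 0.03). The glucose transporter SLC2A1, on both lists, fell from 552 ± 17.0 to 289 ± 3.95 CPM (-0.94 ± 0.03). The phosphofructokinases PFKM and PFKL did not pass, at -0.06 and -0.02. Both lists also passed with an estimated correlation, each with an adjusted p of 0.0314, and no other list did.

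**Figure D1:**
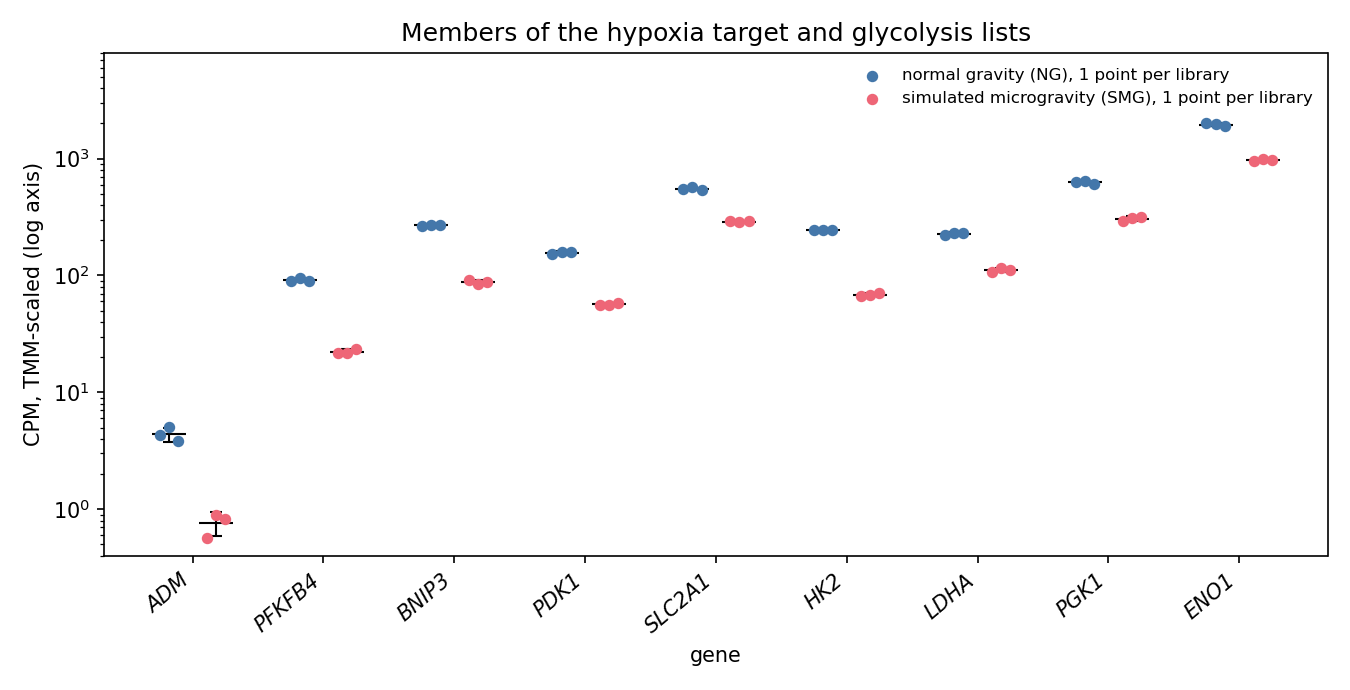
CPM on a log axis of members of the hypoxia target and glycolysis lists in each of the 3 NG and 3 SMG libraries; horizontal lines are group means and bars are SD. In each gene drawn the SMG libraries lie below the NG libraries, with log2 fold changes from -2.50 (ADM) to -0.94 (SLC2A1).

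Other genes among the 10 lowest of the naming rule were on neither list. The hypoxia list holds only a part of the known hypoxia targets, so absence from it does not place a gene outside that response. BHLHE40, a transcriptional repressor, fell from 15.5 ± 0.80 to 0.845 ± 0.110 CPM (-4.18 ± 0.14, edgeR adjusted p = 4.37e-20). STC1, a secreted glycoprotein, fell from 56.8 ± 2.29 to 9.05 ± 0.316 CPM (-2.65 ± 0.06), and its relative STC2 from 64.2 to 19.8 CPM (-1.70 ± 0.05). PLOD2, a collagen lysyl hydroxylase, fell from 114 ± 1.24 to 26.2 ± 1.54 CPM (-2.13 ± 0.05). FGF11 fell from 3.23 to 0.837 CPM (-1.92 ± 0.22).

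The immediate early gene list, of genes induced quickly by growth factors and neuronal activity, had 5 lower and 1 higher among 14 tested members (5 and 1 adjusted over the list alone; camera adjusted p = 0.0339). FOS fell from 13.4 ± 0.706 to 1.67 ± 0.0740 CPM (-3.00 ± 0.12) and EGR1 from 11.4 ± 0.900 to 3.17 ± 0.0621 CPM (-1.85 ± 0.11). BTG2 fell less (-0.25 ± 0.05), and JUN rose (0.32 ± 0.05). The list's adjusted p = 0.347 with an estimated correlation. Camera's adjusted p was 0.076 without NG replicate 2, 0.0805 without SMG replicate 3, 0.0597 with the filter of 1 CPM and 0.0501 over protein-coding genes alone. This list was also fixed beforehand as a sign of RNA or library quality. So were those of mitochondrial mRNAs, replication-dependent histones, cytosolic ribosomal proteins, long neuronal transcripts and heat shock genes, below. Each was called by camera or fry, and whether RNA quality differed between the groups was not tested.

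The motor neuron and cholinergic identity list had 10 higher and 1 lower among 15 tested members (10 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 6.92e-04). The list's adjusted p = 0.129 with an estimated correlation. After removal of a trend with transcript length and GC content, described below, it had 6 higher and 1 lower, with a median of 0.08. FOXP1, a transcription factor of limb-innervating motor neurons, rose from 111 ± 4.42 to 181 ± 6.04 CPM (0.70 ± 0.04). ALDH1A2, the retinoic acid synthesising enzyme found in the same motor columns, rose from 21.8 ± 1.02 to 39.8 ± 1.54 CPM (0.87 ± 0.06). SLC18A3, the vesicular acetylcholine transporter, rose from 51.9 ± 5.26 to 82.4 ± 0.361 CPM (0.66 ± 0.05). MECOM, a transcription factor of the medial motor column, fell from 88.4 to 66.8 CPM (-0.40 ± 0.04). ISL1 rose from 103 to 120 CPM (0.22 ± 0.04, edgeR adjusted p = 5.18e-05).

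MNX1 (0.24 ± 0.05, edgeR adjusted p = 6.03e-04) and LHX3 (0.23 ± 0.07, edgeR adjusted p = 0.0139), transcription factors that specify motor neurons, were higher in SMG. CHAT, the enzyme that makes acetylcholine, was at 30.6 ± 2.60 CPM in NG and 32.4 ± 1.85 in SMG (0.08 ± 0.06, edgeR adjusted p = 0.324). With the trend of transcript length and GC content removed, MNX1 was at 0.07 (adjusted p = 0.223), LHX3 at 0.07 (adjusted p = 0.470) and CHAT at -0.0052 (adjusted p = 0.956). LHX3 also did not pass without SMG replicate 3 (0.15, adjusted p = 0.160).

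**Figure D2:**
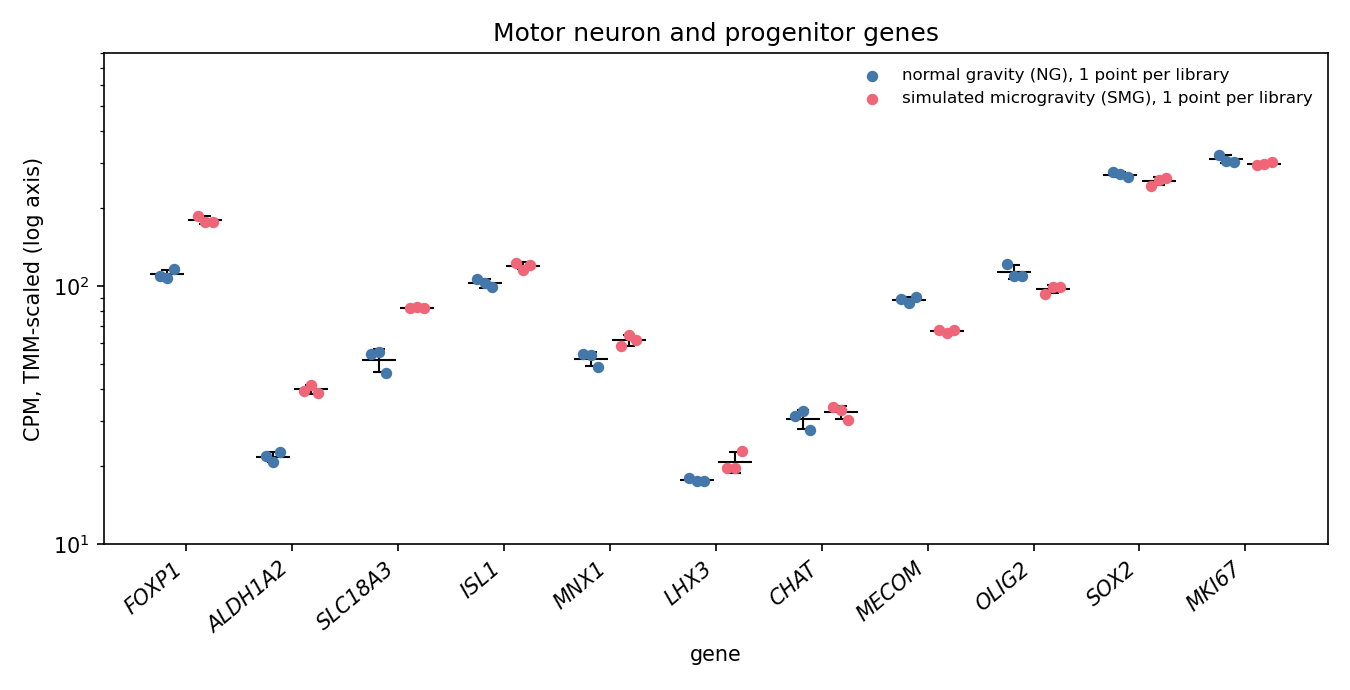
CPM on a log axis of motor neuron and progenitor genes in each of the 3 NG and 3 SMG libraries; horizontal lines are group means and bars are SD. FOXP1, ALDH1A2 and SLC18A3 lie higher in SMG, MECOM and OLIG2 lower, and CHAT, SOX2 and MKI67 did not pass the test.

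Among voltage-gated sodium, potassium and calcium channels, 21 of 41 tested genes rose and 1 fell (23 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 2.09e-05). The list's adjusted p = 0.222 with an estimated correlation. After removal of the trend it had 14 higher and 1 lower, with a median of 0.10. CACNA1E, an R-type calcium channel, rose from 101 ± 1.07 to 147 ± 4.17 CPM (0.54 ± 0.04), and the potassium channel KCNMA1 from 55.6 to 74.1 CPM (0.41 ± 0.04). KCNJ6, an inwardly rectifying potassium channel, rose from 1.52 ± 0.226 to 2.97 ± 0.140 CPM (0.95 ± 0.18). Of neuronal microtubule and neurofilament genes, 16 of 30 rose and 2 fell (18 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 5.47e-05; adjusted p = 0.0896 with an estimated correlation). MAP1B, a microtubule-associated protein, rose from 2393 to 2866 CPM (0.26 ± 0.03), and the axonal kinesin KIF5A from 321 to 380 CPM (0.24 ± 0.03). TUBB3, the neuronal tubulin, rose from 16.5 to 26.0 CPM (0.65 ± 0.07), but the gene overlaps another annotated gene on the same strand and its value is uncertain.

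Other neuronal lists were not called by camera. Fry, which asks whether a list moved in a direction without comparing it with other genes, called 5 of them higher: axon guidance and the glutamate, GABA and glycine receptors (each adjusted p = 0.00196), synaptic vesicle and release (0.00627), and acetylcholine receptors and long neuronal transcripts (each 0.0389). Synaptic vesicle and release genes had 9 higher and 2 lower of 24 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0517), with the presynaptic scaffold BSN at 0.52 ± 0.04, or 0.29 after removal of the trend. Axon guidance genes had 21 higher and 8 lower of 48 (21 and 9 adjusted over the list alone; camera adjusted p = 0.0565). After removal of the trend they had 17 higher and 12 lower, and the median went from 0.05 to 0.01 (camera adjusted p = 0.456). The guidance ligand SLIT3 rose from 330 ± 13.9 to 514 ± 4.96 CPM (0.64 ± 0.03) and the receptor NRP1 from 127 to 188 CPM (0.57 ± 0.03). Receptors for glutamate, GABA and glycine with their scaffolds had 10 higher and 2 lower of 33 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0802). GRIN1, an NMDA receptor subunit, rose from 9.09 ± 0.980 to 15.2 ± 0.459 CPM (0.74 ± 0.09). Acetylcholine receptor and neuromuscular junction genes had 5 higher and 1 lower of 14 (the same counts adjusted over the list alone; camera adjusted p = 0.217), with the muscarinic receptor CHRM3 at 0.28 ± 0.04. Neurotrophic factors and their receptors had 4 higher and 4 lower of 16 (4 and 4 adjusted over the list alone; camera adjusted p = 0.695), with the GDNF receptor RET at 0.45 ± 0.04. Motor neuron disease genes had 7 higher and 8 lower of 27 (8 and 10 adjusted over the list alone; camera adjusted p = 0.761), with SOD1 at -0.30 ± 0.04. Long neuronal transcripts had 7 higher and 4 lower of 20 (8 and 5 adjusted over the list alone; camera adjusted p = 0.695), with RBFOX1 at 0.26 ± 0.04 and CDH12 at -0.51 ± 0.07.

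Of 75 tested genes of cytosolic ribosomal proteins, 63 fell and 0 rose (67 and 0 adjusted over the list alone). The median was -0.33 and the camera adjusted p was 1.11e-20, with an adjusted p = 0.0896 with an estimated correlation. RPL27 fell from 423 ± 18.3 to 303 ± 6.50 CPM (-0.48 ± 0.03), RPL24 from 382 to 279 CPM (-0.45 ± 0.03) and RPS3 from 916 to 690 CPM (-0.41 ± 0.03). These genes share sequence with many processed pseudogenes, and how reads that map to several places were counted is not given in the sources used here, so their values are uncertain.

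Nuclear-encoded genes of respiratory complexes II to V had 23 lower and 0 higher of 38 (23 and 0 adjusted over the list alone; median -0.18, camera adjusted p = 4.71e-06; adjusted p = 0.222 with an estimated correlation). Those of complex I had 16 lower and 2 higher of 38 (18 and 3 adjusted over the list alone; median -0.16, camera adjusted p = 0.00386; adjusted p = 0.253 with an estimated correlation). NDUFB4 of complex I fell from 75.9 to 56.2 CPM (-0.43 ± 0.05), UQCRC2 of complex III from 191 to 163 CPM (-0.23 ± 0.04) and ATP5MC3 of the ATP synthase from 119 to 99.1 CPM (-0.26 ± 0.04). Of the 13 mRNAs encoded in the mitochondrial genome, 3 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.28, camera adjusted p = 0.0487; adjusted p = 0.806 with an estimated correlation). MT-CO3 rose from 3045 ± 243 to 3525 ± 108 CPM (0.21 ± 0.05). The call of that list ended without NG replicate 1 (camera adjusted p = 0.0988), NG replicate 2 (0.151), SMG replicate 2 (0.270, median 0.09) or SMG replicate 3 (0.0545). It also ended with fry (0.263), with DESeq2's size factors (0.0512), with the filter of 1 CPM (0.0541), over protein-coding genes alone (0.0501) and with the smaller prior count (0.05). Mitochondrial biogenesis and dynamics genes had 4 higher and 2 lower of 19 (2 and 1 adjusted over the list alone; camera adjusted p = 0.918), with the nuclear receptor ESRRA at 0.46 ± 0.07 and the coactivator PPRC1 at 0.43 ± 0.05.

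The integrated stress response list had 14 lower and 0 higher of 24 (15 and 0 adjusted over the list alone; median -0.22, camera adjusted p = 1.43e-04; adjusted p = 0.0896 with an estimated correlation). DDIT4, an inhibitor of mTORC1 that also responds to low oxygen, fell from 81.6 ± 6.94 to 42.5 ± 1.51 CPM (-0.94 ± 0.05). The transcription factor ATF4 fell from 231 to 194 CPM (-0.25 ± 0.04). Antioxidant defence genes had 9 lower and 0 higher of 22 (9 and 0 adjusted over the list alone; median -0.10, camera adjusted p = 0.0311; adjusted p = 0.222 with an estimated correlation). The peroxiredoxin PRDX4 fell from 38.6 to 27.3 CPM (-0.50 ± 0.06) and the superoxide dismutase SOD1 from 94.7 to 76.7 CPM (-0.30 ± 0.04). Without NG replicate 1 or 2 the antioxidant list was no longer called (camera adjusted p = 0.0526 and 0.0658), nor over protein-coding genes alone (0.0586). Its median was -0.15 without NG replicate 3.

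The cell cycle list had 15 lower and 2 higher of 32 (17 and 2 adjusted over the list alone; median -0.12, camera adjusted p = 6.22e-04; adjusted p = 0.0919 with an estimated correlation). The topoisomerase TOP2A fell from 558 ± 27.2 to 429 ± 7.89 CPM (-0.38 ± 0.03), the checkpoint kinase BUB1 from 69.9 to 52.0 CPM (-0.43 ± 0.05) and the centromere protein CENPF from 356 to 290 CPM (-0.30 ± 0.03). MKI67 was at 310 ± 11.4 CPM in NG and 298 ± 3.56 in SMG (-0.06 ± 0.03, edgeR adjusted p = 0.185), and at -0.12 after removal of the trend (adjusted p = 0.00156). Neural progenitor genes had 3 higher and 3 lower of 14 (3 and 5 adjusted over the list alone; camera adjusted p = 0.916), or 1 higher and 4 lower after removal of the trend, with SOX2 at -0.08 ± 0.03 (edgeR adjusted p = 0.0599, or 0.0153 without NG replicate 3). Ventral spinal progenitor patterning genes had 1 higher and 3 lower of 10 (1 and 3 adjusted over the list alone; camera adjusted p = 0.761). After removal of the trend the patterning list had 0 higher and 4 lower, and its median went from -0.0309 to -0.125 (camera adjusted p = 0.15). OLIG2, which marks motor neuron progenitors, fell from 113 to 97.2 CPM (-0.22 ± 0.04), and the proneural factor NEUROG2 from 87.7 to 72.3 CPM (-0.28 ± 0.04).

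Extracellular matrix genes had 17 lower and 6 higher of 38 (17 and 6 adjusted over the list alone; median -0.12, camera adjusted p = 0.0152; adjusted p = 0.222 with an estimated correlation). After removal of the trend the matrix list had 24 lower and 4 higher, with a median of -0.25. COL5A2 fell from 180 to 133 CPM (-0.43 ± 0.04) and the proteoglycan VCAN from 476 to 364 CPM (-0.39 ± 0.04), whereas NCAN, a proteoglycan of neural tissue, rose from 122 to 179 CPM (0.55 ± 0.04). Mechanically responsive lists were called by neither camera nor fry's directional test. Fry's mixed test, which lets members move either way, called 48 of the 49 lists, these among them. Focal adhesion and actomyosin genes had 10 higher and 9 lower of 33 (11 and 9 adjusted over the list alone; camera adjusted p = 0.806), or 6 higher and 7 lower after removal of the trend, with ACTB rising from 1875 to 2383 CPM (0.35 ± 0.03). Targets of YAP and TAZ had 5 higher and 4 lower of 15 (6 and 5 adjusted over the list alone; camera adjusted p = 0.770), or 1 higher and 5 lower after removal of the trend, with DLC1 at -0.16 ± 0.04. SRF and cytoskeletal immediate targets, a list without FOS and EGR1, had 2 higher and 3 lower of 11 (2 and 3 adjusted over the list alone, camera adjusted p = 0.681).

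**Figure D3:**
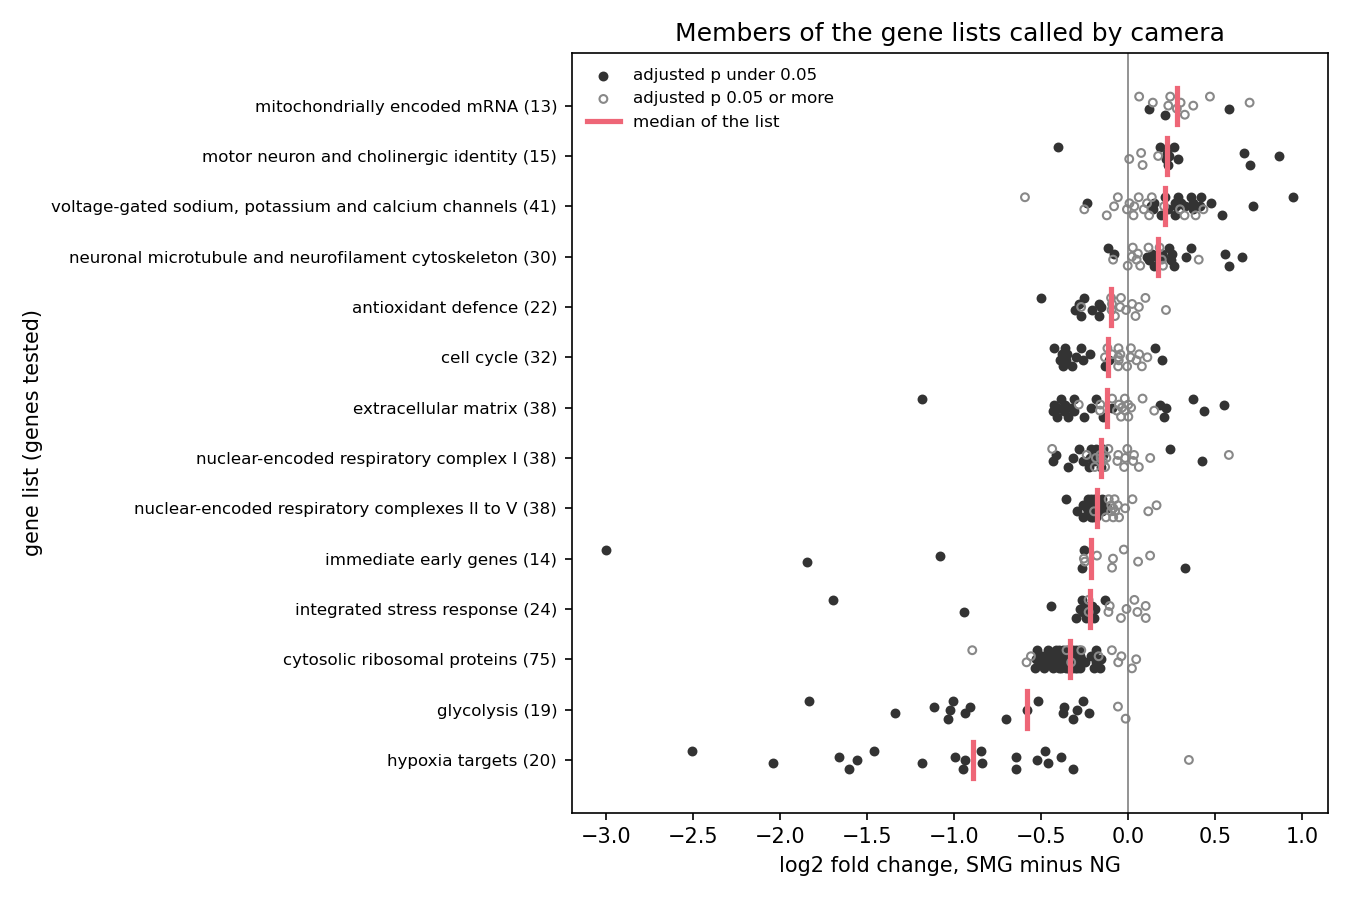
Log2 fold change of each tested member of the 14 lists called by camera, filled where the gene's edgeR adjusted p was under 0.05, with the median of each list as a vertical line. The hypoxia target list has a median of -0.89, the glycolysis list -0.58, and the lists called higher have medians from 0.17 to 0.28.

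Positional and signalling lists were not called by camera, while fry called HOX genes of paralog groups 1 to 5 (adjusted p = 0.0125) and retinoic acid targets (0.00614) lower. HOX genes of paralog groups 1 to 5 had 7 lower and 1 higher of 15 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0802, or 0.0162 and lower after removal of the trend, where adjusted p = 0.275 with an estimated correlation), with HOXB1 at -0.54 ± 0.07. Those of groups 6 to 13 had 6 higher and 3 lower of 12 (6 and 3 adjusted over the list alone; camera adjusted p = 0.637), with HOXC9 at 0.35 ± 0.06 and HOXB9 at -0.21 ± 0.03. Retinoic acid targets had 3 higher and 5 lower of 13 (3 and 5 adjusted over the list alone; camera adjusted p = 0.637), and their median (0.05) and mean (-0.22) differed in sign. After removal of the trend this list had 4 higher and 5 lower, with a median of -0.08 (camera adjusted p = 0.27). The retinoic acid degrading enzyme CYP26A1 fell from 10.4 ± 0.776 to 3.56 ± 0.106 CPM (-1.54 ± 0.11) and the retinoic acid binding protein CRABP2 from 165 to 111 CPM (-0.58 ± 0.05). Targets of TGF-beta and BMP had 1 higher and 2 lower of 10 (1 and 2 adjusted over the list alone; camera adjusted p = 0.396), with ID2 at -0.58 ± 0.06. Notch genes had 4 higher and 2 lower of 18 (4 and 4 adjusted over the list alone; camera adjusted p = 0.831), with NRARP at -0.37 ± 0.04. After removal of the trend the Notch list was called lower, with 0 higher and 7 lower, a median of -0.09 and a camera adjusted p of 0.0230 (adjusted p = 0.370 with an estimated correlation). Hedgehog targets had 3 higher and 2 lower of 8 (4 and 2 adjusted over the list alone; camera adjusted p = 0.637), with HHIP at -0.42 ± 0.10. Wnt targets had 1 higher and 1 lower of 9 (1 and 1 adjusted over the list alone; camera adjusted p = 0.791), with TCF7 at 0.48 ± 0.10.

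The remaining lists of stress, cell death, metabolism and immune genes and histones, given in this paragraph, were not called by camera. Fry called p53 targets (adjusted p = 0.00627), apoptosis regulators (0.00293) and heat shock genes (0.00726) lower and replication-dependent histones (0.0408) higher. Targets of p53 had 3 higher and 8 lower of 22 (3 and 9 adjusted over the list alone; camera adjusted p = 0.0517, or 0.00562 and lower after removal of the trend, where adjusted p = 0.158 with an estimated correlation), with the cell cycle inhibitor CDKN1A falling from 48.2 to 33.2 CPM (-0.54 ± 0.05). Apoptosis regulators had 2 higher and 4 lower of 23 (1 and 3 adjusted over the list alone; camera adjusted p = 0.695). BNIP3L, a mitophagy receptor on that list, fell from 399 to 283 CPM (-0.50 ± 0.03). Heat shock genes had 2 higher and 6 lower of 15 (2 and 6 adjusted over the list alone; camera adjusted p = 0.143), with HSP90AB1 at -0.25 ± 0.03. Endoplasmic reticulum chaperones had 3 higher and 7 lower of 20 (3 and 7 adjusted over the list alone; camera adjusted p = 0.770), with CANX at -0.22 ± 0.03. Autophagy and lysosome genes had 5 higher and 7 lower of 25 (6 and 7 adjusted over the list alone; camera adjusted p = 0.892), with LAMP1 at 0.29 ± 0.04. Cholesterol synthesis genes had 5 higher and 5 lower of 23 (5 and 5 adjusted over the list alone; camera adjusted p = 0.803), with STARD4 at -0.46 ± 0.04. Interferon response genes had 2 higher and 2 lower of 9 (3 and 2 adjusted over the list alone; camera adjusted p = 0.831), with IFIT1 at -0.85 ± 0.22. The list of NF-kappaB and cytokine genes had 1 higher and 1 lower of 5 (1 and 1 adjusted over the list alone; camera adjusted p = 0.803), with CXCL12 at 0.33 ± 0.08. Replication-dependent histones had 3 higher and 0 lower of 5 (3 and 0 adjusted over the list alone; camera adjusted p = 0.174), with H2BC21 at 0.32 ± 0.06.

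No list of markers of another cell type was called by camera, while fry called astrocyte markers lower (adjusted p = 0.0116). Spinal interneuron markers had 3 higher and 1 lower of 16 (3 and 1 adjusted over the list alone; camera adjusted p = 0.396), or 1 higher and 2 lower after removal of the trend, with GAD1 falling from 5.75 to 3.70 CPM (-0.63 ± 0.12). GATA2 rose from 0.479 to 1.03 CPM (1.08 ± 0.33), but did not pass without SMG replicate 1 (adjusted p = 0.052) or 2 (0.0755). LMX1B (1.35 ± 0.47) and EN1 (0.73 ± 0.26), named after their values were seen, also rose, both from under 1 CPM in NG. Markers of sensory neurons, neural crest and Schwann cells had 1 higher and 1 lower of 8 (camera adjusted p = 0.770), with NGFR at 0.39 ± 0.03, or 0.23 after removal of the trend. Astrocyte markers had 2 lower and 0 higher of 5 (camera adjusted p = 0.310), with GJA1 falling from 36.4 to 24.7 CPM (-0.56 ± 0.07). Oligodendrocyte lineage markers had 1 higher and 1 lower of 7 (camera adjusted p = 0.831), with CNP at 0.31 ± 0.05. Mesenchymal and fibroblast markers had 1 lower of 7 (camera adjusted p = 0.681) and endothelial markers 2 lower of 5 (camera adjusted p = 0.637). These were PDGFRB (-0.79 ± 0.26), KDR (-0.82 ± 0.32) and TIE1 (-0.36 ± 0.12), and none of them passed without NG replicate 1 (adjusted p = 0.088, 0.0741 and 0.161). Counts adjusted over each list alone were the same for these 5 lists. A further 6 lists had fewer than 5 tested members and no list test. Among them, 1 of 2 cranial motor neuron genes rose (TBX3, from 0.749 to 1.70 CPM), 1 of 3 skeletal muscle genes rose (MYH3, 0.52 ± 0.13), and 2 of 4 epithelial and endodermal genes fell (KRT8 at -0.39 ± 0.11 and CDH1 at -1.63 ± 0.42). KRT8 did not pass without NG replicate 1 (adjusted p = 0.0737). Of 3 pluripotency genes DNMT3B rose (0.17 ± 0.04, or 0.11 after removal of the trend) and LIN28A fell (-0.17 ± 0.05, or -0.11 with an adjusted p of 0.130 without SMG replicate 1). Of 3 floor plate genes 1 rose, NKX2-2 (0.38 ± 0.14), which did not pass with DESeq2 (adjusted p = 0.149) or in 5 of the 6 fits without a library (adjusted p from 0.0578 to 0.117). The 1 microglia and blood gene tested did not pass. The counts over these lists alone were the same.

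The 10 highest genes of the naming rule were mostly weakly expressed. HPX, the heme-binding hemopexin, rose from 1.69 ± 0.197 to 3.30 ± 0.374 CPM (0.96 ± 0.17), and ARPP21, a regulator of calmodulin signalling, from 2.81 ± 0.508 to 5.21 ± 0.626 CPM (0.91 ± 0.15). GARIN1A (0.93 ± 0.18) and BTBD19 (0.92 ± 0.15) also rose. The non-coding gene GPC1-AS1 (0.85), the antisense genes PTOV1-AS2 (0.92) and SFTPD-AS1 (0.87) and the pseudogene SH3GL1P3 (0.93) rose as well. PTOV1-AS2, SFTPD-AS1 and SH3GL1P3 overlap genes on the opposite strand, and whether counting used strand is not given in the sources used here, so their values are uncertain. Of the 147 named genes, 48 share more than 50 bases of exon with another annotated gene, among them ALDH1A2, FOXP1, KCNJ6, FGF11, PFKFB4, SLC2A1, PGK1 and ENO1, and their values are uncertain to that extent.

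Log2 fold changes rose with the GC content of the transcript. Over 10283 genes with a mean of 10 CPM or more, Spearman's correlation across genes, which are not independent replicates, was 0.486 with GC content and 0.161 with length. The median log2 fold change was -0.11 in the lowest of 5 equal bins of GC content and 0.16 in the highest. With the trend removed, the median of the motor neuron identity list went from 0.22 to 0.08 (camera adjusted p = 0.00475) and its higher members from 10 to 6, with 1 lower. The median of the channel list went from 0.21 to 0.10 (0.00196) and its higher members from 21 to 14, the median of complex I from -0.16 to -0.10 (0.00319) and that of the extracellular matrix list from -0.12 to -0.25 (3.50e-06). The hypoxia targets stood at -0.95 and the glycolysis genes at -0.56 after removal. With an estimated correlation these lists passed after removal (adjusted p = 0.0308 and 0.0305), and the other lists called after removal had adjusted p from 0.0509 to 0.580. The share of counts from mitochondrial mRNAs was 2.23% ± 0.115 in NG and 2.62% ± 0.269 in SMG, and that from mitochondrial rRNA was 0.560% ± 0.0380 and 0.489% ± 0.0163.

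**Figure D4:**
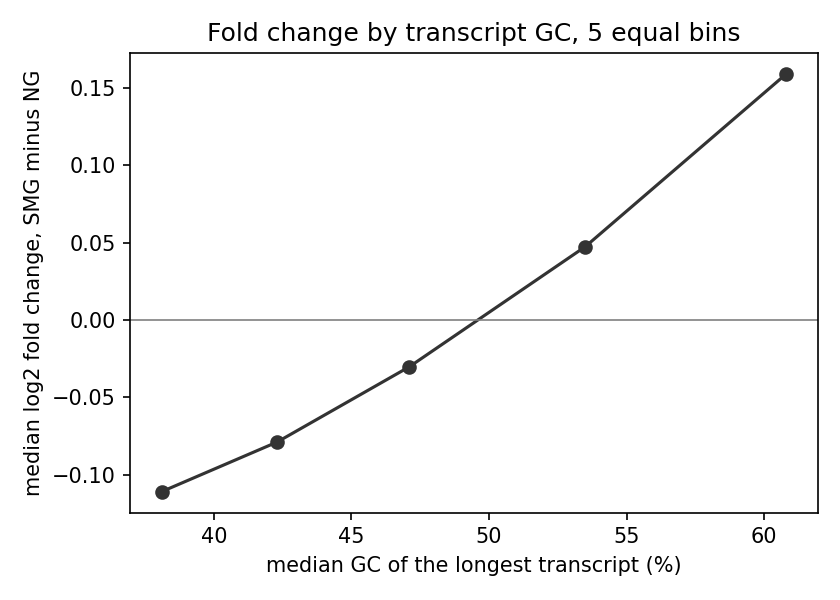
Median log2 fold change (SMG minus NG) of each of 5 equal bins of 10283 genes ordered by GC content of the longest transcript, against the median GC content of the bin in percent. The medians go from -0.11 at 38.1% GC to 0.16 at 60.8% GC.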

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

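The removal of the length and GC trend and the restriction to protein-coding genes were chosen after the data were seen. The count of changed genes stayed within 1.5 times of 6376 under each setting run, and was 4648 with DESeq2, which left 286 of the 6376 without an adjusted p, 6225 with limma-voom and 5398 with the trend removed, of which 4278 were shared with the 6376. Without each library in turn it ranged from 4961 to 6092, and the count at 2-fold from 173 to 217. The counts at 2-fold moved with the filter, from 166 (78 higher, 88 lower) to 261 (119 and 142) with no filter and 76 (24 and 52) with at least 1 CPM in 3 samples, since weakly expressed genes enter or leave the test. Of the 166, 77 higher and 53 lower genes had a mean under 2 CPM, where depth limits the precision. Over protein-coding genes, which are fewer, the count was 87 (32 and 55). With DESeq2 on the same genes it was 43 (6 and 37), and the cause was not tested. Lists called higher went from 4 to 7 with no filter, to 9 with fry (16 lower) and to 0 with an estimated correlation (2 lower, hypoxia targets and glycolysis). Without each library in turn, hypoxia targets and glycolysis were called in each of the 6 fits, and 2 to 8 of 147 named genes no longer passed. With the trend removed, 13 of 147 named genes no longer passed, MKI67 passed (-0.12), and CHAT, which had not passed, went from 0.08 to -0.0052. The cause was not tested. With DESeq2, 137 of 142 named genes with an adjusted p kept their direction and side of the threshold, and with limma-voom and the other scalings 147 of 147.

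The counts gave no sign that the replicate numbers pair the libraries. Deviations of libraries with the same number had correlations of -0.0590, 0.0440 and -0.0566 across genes, and no library correlated best with its own number. Such correlations cannot show whether libraries with the same number were cultured or prepared together. With the replicate block 6333 genes were called, 6208 of them shared, lists stayed at 4 higher and 10 lower, and among named genes KDR alone changed side (adjusted p = 0.0566).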

Other observations

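A scan of gene families by symbol prefix, the comparison of cycling progenitors with the cell cycle list, and the removal of the length and GC trend were chosen after the results were seen. Of 163 families of at least 10 tested genes that share a symbol prefix, 7 were called by camera, 6 lower and 1 higher in SMG, of which 3 (RPL, RPS and MRPL) passed after removal of the trend, and none passed with an estimated correlation (adjusted p from 0.693 to 0.822). The mitochondrial ribosomal proteins of the large subunit (MRPL) had 22 lower and 1 higher of 47, with a median log2 fold change of -0.19 (camera adjusted p = 0.00397, or 0.0113 after removal of the trend; adjusted p = 0.693 with an estimated correlation). The calcium channel genes (CACNA) had 6 higher and 0 lower of 11, with a median of 0.30 (camera adjusted p = 0.0446, or 0.301 after removal of the trend; adjusted p = 0.822 with an estimated correlation). Both mitochondrial rRNAs fell, MT-RNR1 from 536 to 383 CPM (-0.48 ± 0.04) and MT-RNR2 from 5117 to 4481 CPM (-0.19 ± 0.05), while 0 of 13 mitochondrial mRNAs fell.

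By gene type, 124 antisense genes were higher and 53 lower of 1107 tested, whereas 30 processed pseudogenes were higher and 84 lower of 611. Sense intronic genes had 21 higher and 6 lower of 130. Strand and multi-mapping settings are not given in the sources used here, so reads of these classes may belong to other genes, and with protein-coding genes alone 5716 genes were called.

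The first pattern is the fall of hypoxia targets and glycolysis genes. The trend with length and GC is not its cause, since the higher of the medians of both lists after removal was -0.56, nor is a single library, since both lists were called in 6 of 6 fits without a library. A second list of 22 hypoxia targets, none of them on the first list and drawn up after that list's fall was seen, had 12 lower and 4 higher, with a median of -0.34 (one-list camera p = 7.86e-05, or 0.0244 with an estimated correlation); RORA (-1.01) and GBE1 (-0.81) fell, and QSOX1 (0.21) rose. A candidate explanation is lower activity of hypoxia-inducible factors in SMG. Whether that may come from rotation itself or from oxygen supply, vessel or cell density, none of which is given in the sources used here, stays open.

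The second pattern is the rise of fold with GC content, along with lower ribosomal protein and respiratory genes and higher ion channels. After removal of the trend the ribosomal list stood at -0.30, the lower of the adjusted p of both respiratory lists was 1.34e-04, and the channel list stood at 0.10 from 0.21, so with the preset correlation the trend is not the whole of these changes but may be a part of them (adjusted p from 0.0509 to 0.275 with an estimated correlation). A bias of library preparation with GC could give such a trend, and would act on every class of transcript. Spearman's correlation of fold with GC content across genes was 0.455 in 12099 protein-coding genes (0.288 in the 2223 of them under 10 CPM), 0.149 in 888 long non-coding genes and 0.0225 in 222 processed pseudogenes, so the pseudogenes lay below the bound of 0.1 set beforehand against such a bias and the long non-coding genes between it and the bound of 0.2 set for it. The slope per 10% GC was -0.10 to -0.02 in the NG libraries and 0.04 to 0.07 in the SMG libraries. Slopes were fitted to deviations from each gene's mean over all libraries, so opposite signs in the groups are partly forced. The NG libraries also differed among themselves (-0.046, -0.0178 and -0.104 for replicates 1, 2 and 3). Bias in preparation and a real change of GC-rich genes cannot be told apart, because each could follow the groups.

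The third pattern is the higher motor neuron identity list with the lower cell cycle list. With the preset correlation the values argue against the trend as its whole cause, as the higher of the adjusted p of both lists after removal was 0.00475 (0.153 with an estimated correlation), although the higher members of the identity list went from 10 to 6 and its median from 0.22 to 0.08. A smaller share of cycling progenitors might lower the cell cycle genes, and would lower progenitor genes with them. The progenitor list had a median of 0.00971 against -0.12 for the cell cycle list, a difference of 0.13 (two-sided permutation p = 0.0683). Genes and not libraries were permuted between the lists, so this p treats genes that may change together as independent. After removal of the trend the medians were -0.04 and -0.12, a difference that was not tested. The ventral spinal progenitor patterning list then had a median of -0.125 (camera adjusted p = 0.15). The permutation p above misses the threshold. A comparison of gene lists in bulk RNA also cannot separate the share of cycling cells from the rate of their cycle, whatever its p. A smaller share of cycling progenitors and a slower cycle therefore cannot be told apart.

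The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05, and 1 of the 10, the real one, gave as many in each of the following counts. The real split gave 6376 changed genes and the highest other 0. At 2-fold the real split gave 166 and the highest other 0. For lists the real split gave 14 and the highest other 10, with the preset correlation. Each other split mixes SMG and NG libraries on both sides, so the difference between the groups adds to its spread. Such splits can give 0 changed genes whatever the cause of that difference, and their called lists can carry a part of it. These counts therefore do not measure how often chance gives such values.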
